A study of Rattus norvegicus with 8 samples.

How the data were processed

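Polyadenylated RNA from 8 wells of primary neonatal rat cardiomyocytes, grown in medium with 2% serum, was sequenced from stranded libraries made by ligation, per the labels' protocols. Libraries were grouped by their titles into 4 controls and 4 treated with GDF10, numbered 1 to 4 in each group. The protocol also describes treatments with BMP2 and activin A, which were not analysed here. The wells are described as independent cultures. Whether they came from separate isolations or animals is not given in the sources used here, so p-values measure the spread between wells.

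The authors deposited 1 quantification table per library with 41078 Ensembl rat transcripts. STAR and Salmon and the builds rn6 and Rnor_6.0 are named in the submitters' processing notes, without versions, and the annotation release is not given in the sources used here. Per the file headers, each table gives the transcript's length, its effective length in bases, its TPM and the estimated count of reads. The deposited TPM values are scaled to the same sum in each library. The deposited estimated counts are not all whole, because a read that fits several transcripts is divided among them. Such division can move reads between overlapping transcripts of a gene from library to library, which adds spread to single transcripts. Of the 17129 transcripts tested, 8252 (48.2%) had counts within 0.0005 of a whole number in all 8 libraries.

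The reference table used here (assembly GRCr8, 47357 genes) pairs no Ensembl identifier with a gene, and 0 of the identifiers in the files matched it. Reads were therefore not summed per gene. Each transcript was kept as its own feature, as the design fixed before the data were examined allows, and the tests of 27 gene lists and the settings planned for them were not run. Positions, exons and gene names of the transcripts are not reported. The planned rule for named genes took, if fewer than 10 passed the threshold, those with the smallest p, a mean of at least 2 TPM and complete separation of the groups. It was applied to transcripts and limited to 2 that rose and 2 that fell, because unnamed identifiers inform little. This departs from the plan, which asked for a gene symbol and kept transcripts without a gene out of named results. The rule's parts on listed genes could not be applied.

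Estimated counts were rounded to whole numbers. Transcripts with low counts were removed with filterByExpr of edgeR 4.0.16 in R 4.3.3, which kept 99.9% of the reads, and libraries were scaled with TMM factors. The main test was edgeR's robust quasi-likelihood test of GDF10 against control over all 8 libraries without covariates, with Benjamini-Hochberg adjustment over all transcripts tested and a threshold of 0.05. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. CPM values were computed with the TMM factors, and log2 values for correlations used a prior count of 2. Library totals of 20478332 to 29933655 reads limit the precision of each value, and intervals from replicates cover the spread between wells only.

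Pairing was checked through the correlation of the libraries' deviations from their group mean. Same-numbered libraries had correlations of 0.217, 0.220, 0.170 and 0.211, all over the 0.1 set as the minimum, so the numbers were taken as pairing the samples and the blocked fit is given beside the main one. Libraries of the other group with another number from the same subset (1 and 2, or 3 and 4) had correlations between 0.110 and 0.185, and 6 of 8 libraries were closest to their own number. These also pass the minimum of 0.1, so the check does not tell pairing by number apart from a shared subset. The fit with the subset as a term, fits within each subset and the subset by treatment interaction were added after these correlations were seen.

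The alternatives planned before the data were examined were the replicate block, size factors of DESeq2 1.42.0 and upper quartile scaling, no filter or a filter of 1 CPM in 4 libraries, DESeq2's own test, limma-voom (limma 3.58.1), limma on log2(TPM + 0.5) and log2(TPM + 1), effective length offsets, 1 surrogate variable (sva 3.50.0), a fold minimum of 1.5, a test against a fold of 1.2, and leaving out each library. DESeq2's own test took the counts before filterByExpr. It adjusted p after its own default filter on mean counts. The transcripts given below as having a p-value in DESeq2 may therefore outnumber those with an adjusted p. A fit at transcript level had been planned as an alternative and here is the main fit. Added alternatives were the subset term, transcripts with whole counts only, and offsets from a lowess trend (span 0.3) of each library on transcript length.

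The fits were tested on 1 simulated data set with the means, library sizes, subset differences and dispersions of the 17129 transcripts. Of these transcripts, 200 with a mean of at least 100 reads were changed. Of 50 transcripts changed 2-fold, 40 were recovered without a block, 45 with the block and 47 with the subset term. Of 50 changed 1.5-fold, 18, 36 and 36 were recovered, and of 50 changed 1.25-fold, 1, 16 and 17. False calls numbered 4, 15 and 16 of 108, 161 and 165 calls. With the block and with the subset term, their share was thus above the rate that the adjusted p threshold is meant to hold. Without a block it was below that rate. The rate is a mean over repeats, which 1 simulated data set does not measure. Figures were drawn with matplotlib 3.10.9.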

Results

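RNA-seq libraries of primary cardiomyocytes from neonatal rats were compared after culture with or without GDF10, a secreted ligand of the TGF-beta superfamily. The cells, the contractile cells of the heart taken directly from newborn animals, had grown for about 40 hours before a treatment of 48 hours. Each group held 4 libraries from independent culture wells. The protocol names GDF10 at 10 or 50 ng/uL and does not say which of these doses the sequenced wells received. Total estimated reads per library were 24540484 ± 3767725 (SD, n = 4) in the controls, with a range from 21203310 to 29933655, and 21568409 ± 958560 (SD, n = 4) with GDF10, with a range from 20478332 to 22802983. Between 20939 and 21953 of the 41078 annotated transcripts had at least 1 read in a control library, and between 20955 and 21134 in a GDF10 library. The 10 most abundant transcripts took 11.7% ± 0.772 (SD, n = 4) of the reads in the controls and 11.8% ± 0.880 (SD, n = 4) with GDF10. The quantification lists Ensembl transcript identifiers that the gene table used here did not pair with gene names. Results are therefore given per transcript, and the 27 lists of cardiomyocyte maturation, metabolic, cell cycle, signalling and cell type marker genes fixed beforehand were not tested.

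The libraries were first compared with one another, because a difference among replicates sets what the comparison of GDF10 with control can show. In both groups, replicates 1 and 2 resembled each other more than they resembled replicates 3 and 4. The Pearson correlation of log2 CPM (read counts scaled to library size) across 17129 transcripts lay between 0.958 and 0.965 for the 4 pairs of libraries that shared both group and subset of replicate numbers. It lay between 0.949 and 0.961 for the 8 pairs that shared the subset and differed in treatment, and between 0.940 and 0.950 for the 8 pairs that shared the treatment and differed in subset. Replicates 1 and 2 are called subset A below and replicates 3 and 4 subset B. A comparison of subset B with subset A, with treatment in the model, found 5763 transcripts past a Benjamini-Hochberg adjusted p of 0.05 in edgeR's quasi-likelihood test, of which 2822 were higher and 2941 lower in subset B. The share of a transcript's variance that followed the subset had a median of 36.1% and a mean of 40.3%, and the share that followed treatment a median of 8.61% and a mean of 15.8%, where a treatment with no effect would take a mean of 9.95% beside the subsets. No label names a batch, date or isolation, so the subsets are known only from the values. No pair of libraries agreed within sampling noise, since the chi-square per degree of freedom of their counts was at least 5.38, and all 8 were counted separately.

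**Figure D1:**
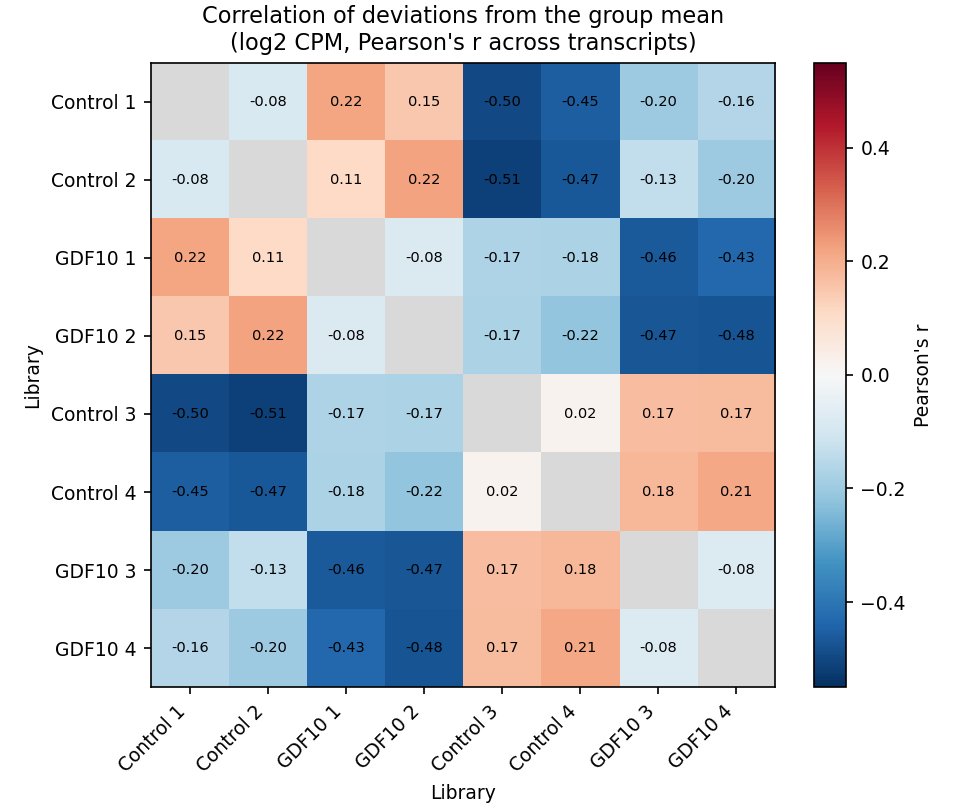
Pearson's r across transcripts between the libraries' deviations from their own group mean in log2 CPM, with libraries in rows and columns ordered by subset and the diagonal left grey. Between groups, libraries of the same subset have r from 0.11 to 0.22 and libraries of different subsets from -0.22 to -0.13.

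The comparison of GDF10 with control asked which transcripts GDF10 changed, in a study titled after cardiomyocyte maturation around birth. The 4 transcripts named here had the smallest p, 2 in each direction, among those with a mean of at least 2 TPM and complete separation of the groups. They differed by less than 2-fold. ENSRNOT00000026793, a transcript of 1436 bases, was at 29.2 ± 2.24 CPM in the controls and 15.9 ± 1.22 with GDF10 (SD, n = 4 each), a log2 fold change of -0.88 with a standard error of 0.08. ENSRNOT00000021630, of 1257 bases, was at 76.2 ± 3.97 CPM in the controls and 43.8 ± 4.44 with GDF10 (SD, n = 4 each), a log2 fold change of -0.80 with a standard error of 0.08. ENSRNOT00000004525, of 10069 bases, was at 49.6 ± 1.42 CPM in the controls and 67.0 ± 2.32 with GDF10 (SD, n = 4 each), a log2 fold change of 0.43 with a standard error of 0.05. ENSRNOT00000071885, of 2942 bases, was at 31.5 ± 0.688 CPM in the controls and 41.7 ± 1.46 with GDF10 (SD, n = 4 each), a log2 fold change of 0.41 with a standard error of 0.05. Their choice required every GDF10 library to lie on one side of every control library, so the separation is no result. Each of the 4 had whole read counts, between 321 and 2384 reads per library.

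None of the 17129 transcripts tested passed an adjusted p of 0.05 when the 4 GDF10 libraries were compared with the 4 control libraries without regard to replicate number, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The smallest adjusted p was 0.0600, shared by ENSRNOT00000026793 and ENSRNOT00000021630. The adjusted p of ENSRNOT00000004525 was 0.0773, and that of ENSRNOT00000071885 was 0.0917. At an unadjusted p under 0.05 there were 1056 transcripts, where 856 would be expected if p were uniform, which the difference between subsets does not ensure. In the same fit, the other splits with 2 libraries of each subset on either side gave 136 to 529 such transcripts. These splits are too few for a share under 0.05. Other tools applied to the same contrast called 155 transcripts (DESeq2 before the filter, 66 higher and 89 lower), 4 transcripts (limma-voom) and 5 transcripts (limma on log2 TPM). Complete separation of the groups, with all 4 GDF10 libraries above or all 4 below the controls, occurred in 785 transcripts or 4.58%, with 372 higher and 413 lower with GDF10.

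Same-numbered libraries deviated together, with a correlation between 0.170 and 0.220 for the 4 numbers. Libraries of the other group with another number from the same subset had 0.110 to 0.185. Pairing by number is thus not clearly told apart from a shared subset. The fit with the replicate number as a block called 65 transcripts. Of these, 29 rose and 36 fell with GDF10. Under the same block DESeq2, run before the filter, called 1071 transcripts, where 25780 had a p-value. Limma-voom called 85 of 17129. When only the 8252 transcripts with whole counts were tested, edgeR called 507. The median fold change was 1.35 among those that rose and 1.41 among those that fell, and 20 of the 65 changed by at least 1.5-fold, 5 upward and 15 downward. The 4 transcripts named above passed in this blocked fit. Their edgeR adjusted p were 0.0351 for ENSRNOT00000026793, 0.0309 for ENSRNOT00000021630, 0.0309 for ENSRNOT00000004525 and 0.0461 for ENSRNOT00000071885. The called transcripts had a higher median abundance than the rest, with 38.1 TPM for those that rose and 40.6 TPM for those that fell, against 11.0 TPM for transcripts not called. Leaving out 1 pair left 0 or 1 call, a loss that a test with fewer degrees of freedom favours whichever pair is removed. At an unadjusted p under 0.05 there were 2554 transcripts with all 4 pairs, and 1833, 1779, 2559 and 2000 without replicate 1, 2, 3 and 4.

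**Figure D2:**
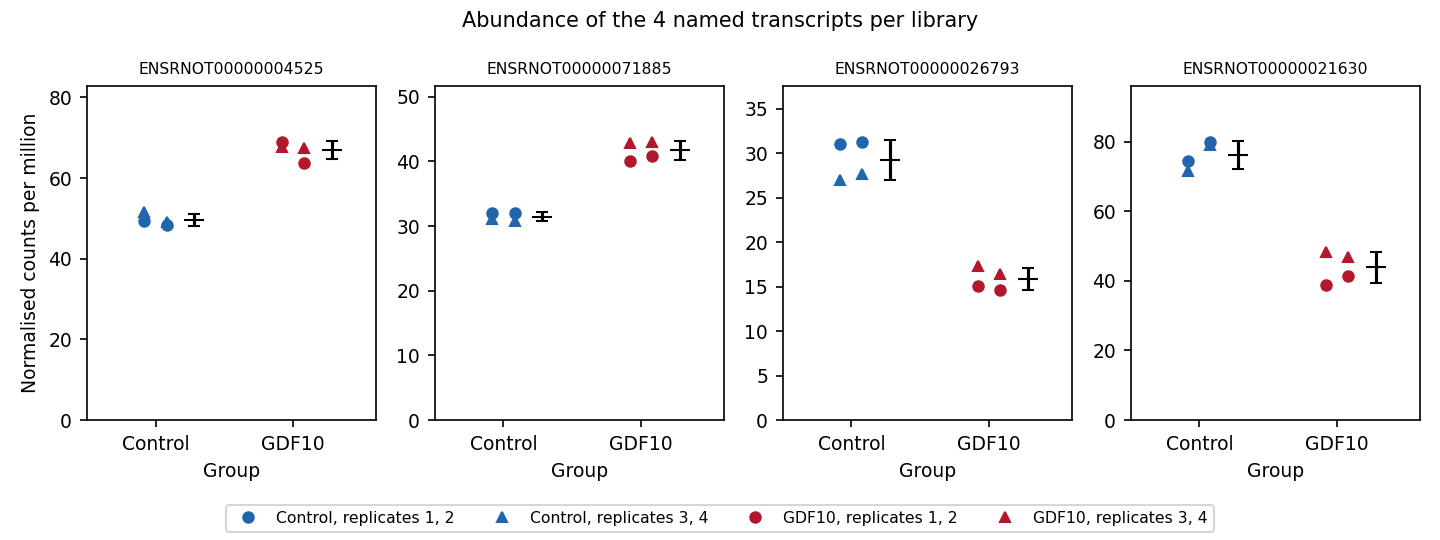
Normalised abundance in CPM (vertical axes, each from 0) of the 4 named transcripts in every control and GDF10 library, with circles for replicates 1 and 2, triangles for replicates 3 and 4, and bars for the mean ± SD of 4 libraries. As their choice required, ENSRNOT00000004525 and ENSRNOT00000071885 are higher in all 4 GDF10 libraries, and ENSRNOT00000026793 and ENSRNOT00000021630 are lower in all 4.

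With the subset of replicates as a term in the model, an alternative chosen after the correlations between libraries were seen, 547 transcripts or 3.19% of those tested passed the threshold. Of these, 260 rose and 287 fell with GDF10, with median fold changes of 1.24 and 1.21. The count and balance depended on the settings. Under the same term DESeq2 before the filter gave 1586 calls (787 higher and 799 lower, 25780 with a p-value). Limma on log2 TPM in place of counts gave 445 (292 higher and 153 lower). Limma-voom on the same filtered counts gave 536 (248 higher and 288 lower). Of the 547, 68 changed by at least 1.5-fold, 30 upward and 38 downward, and 15 by at least 2-fold. The block and subset models shared 63 called transcripts, all 63 with the same direction. The higher and lower sets differed in transcript length, with a median of 2734 bases for those that rose and 2114 bases for those that fell. Among the 3432 shortest transcripts tested, up to 1257 bases, 24 rose and 76 fell, against 236 and 211 in the rest (two-sided Fisher's exact test over transcripts, which are not independent replicates, p = 1.33e-07). In the rest, from the shorter to the longer of 4 groups of similar size, 42 rose and 51 fell, then 57 and 45, then 65 and 35, and 72 and 80 among the longest. The median log2 fold change rose at each step with length, from -0.0345 in the shortest transcripts to -0.0034, 0.0071, 0.0140 and 0.0208 in these groups. Removing a trend with length from each library takes out such a lean by construction, so its outcome is no evidence on the lean. After it, 43 short transcripts rose and 44 fell, against 204 and 241 in the rest (Fisher's exact test, p = 0.558). Leaving out 1 library at a time lowered the count of 547 to between 104 (without control replicate 1) and 454 (without control replicate 3).

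**Figure D3:**
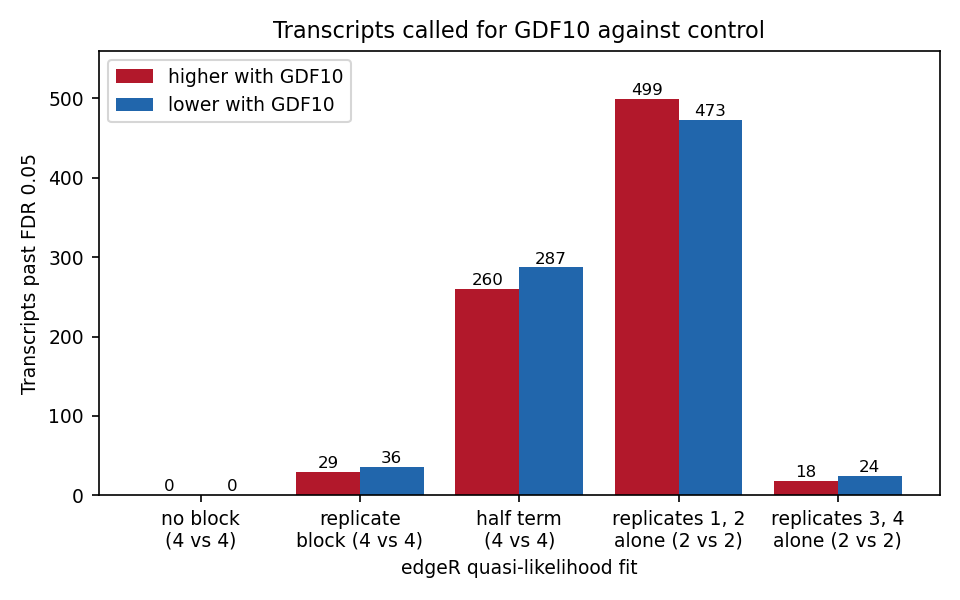
Number of transcripts past an adjusted p of 0.05 in edgeR (vertical axis) that were higher (red) or lower (blue) with GDF10, by model and libraries used (horizontal axis). In the fits drawn with all 8 libraries the counts run from 0 without a block to 260 higher and 287 lower with the subset term. A model with a separate mean for each group and subset, not drawn, called 717 higher and 610 lower for the mean GDF10 effect. Replicates 1 and 2 alone give 499 higher and 473 lower, and replicates 3 and 4 alone 18 and 24.

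Within subset A alone, 2 GDF10 libraries against 2 controls, edgeR's quasi-likelihood test called 972 transcripts, 499 higher and 473 lower. Within subset B alone it called 42, 18 higher and 24 lower. A test of the difference itself, the interaction of subset and treatment, called 314 transcripts. In the same 4-group model the mean GDF10 effect over both subsets called 1327, 717 higher and 610 lower. The subsets share no library. Of the 939 transcripts called in subset A and also tested in subset B, 692 or 73.7% had a fold change in the same direction there, against 56.7% of the 16752 transcripts tested in both. Their median fold change was 1.35 in subset A, and in subset B, taken in the direction seen in subset A, it was 1.07. Of the 35 transcripts called in subset B and tested in subset A, 27 or 77.1% had the same direction there, and their median fold change was 1.61 in subset B and 1.33 in subset A in that direction. A smaller change in the other subset is expected of transcripts chosen for passing in one. Transcripts called in both subsets in the same direction numbered 7 higher and 8 lower, where independent lists would share 0.427 and 0.552. That reference takes every transcript as equally likely to be called. With the replicate block, called transcripts were more abundant than the rest, so the reference may be too low. Overlaps under other pairings were not counted. Pairing the subset B libraries in the other possible ways, each mixing a control with a GDF10 library, gave same-direction shares of up to 67.6% in the better orientation. These shares cover the 941 transcripts called in subset A that the filter over all 8 libraries kept. Thus 50% is too low a reference for the observed share. The log2 fold change of ENSRNOT00000026793 was -1.07 in subset A and -0.70 in subset B. Those of ENSRNOT00000021630 were -0.95 and -0.66, those of ENSRNOT00000004525 were 0.44 and 0.43, and those of ENSRNOT00000071885 were 0.33 and 0.47. Complete separation, for which these transcripts were chosen, fixes the same direction in both subsets.

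**Figure D4:**
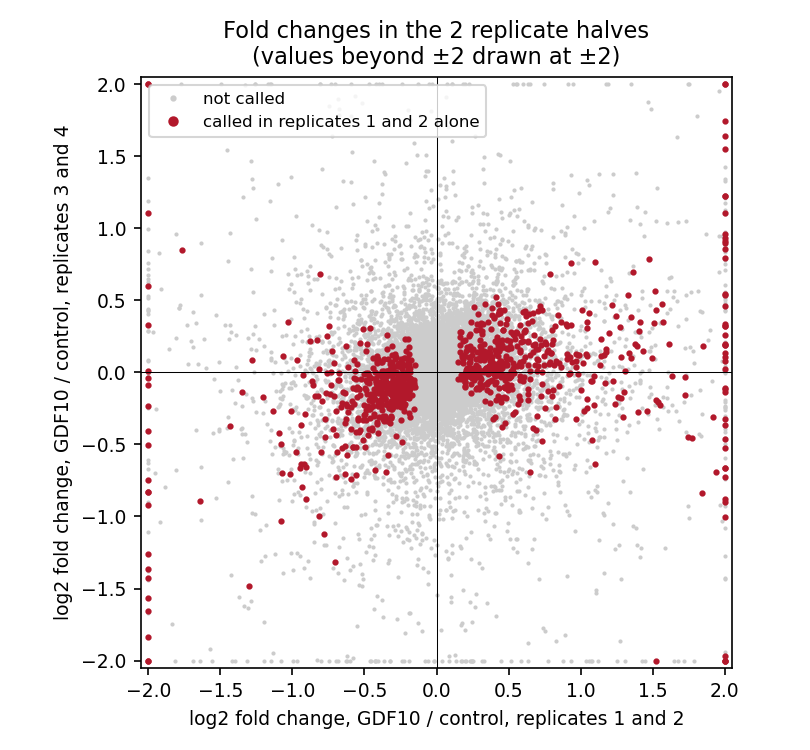
Log2 fold change of GDF10 over control for 16752 transcripts in replicates 1 and 2 (horizontal axis) and in replicates 3 and 4 (vertical axis), with transcripts called in replicates 1 and 2 alone in red, the others in grey, and values beyond 2 drawn at the edge. Of the 939 red points, 692 lie in the quadrants where both fold changes have the same sign.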

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

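The tests of fragment length, abundant transcripts and transcript length on the difference between subsets were set before their results were seen, and the other tests in this part, with the overlaps of calls, after.

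The GDF10 effect differed between replicates 1 and 2 (subset A) and replicates 3 and 4 (subset B) in 314 transcripts by edgeR's interaction test. The effect was higher in subset B for 104 of them and lower for 210. Splits that kept the real groups in subset A and mixed them in subset B gave 53 to 125 interaction calls. The GDF10 contrast called 972 transcripts in subset A and 42 in subset B. Fewer reads in subset B are argued against, since it held 95196283 reads in total and subset A 89239285. With every library thinned at random to the reads of the smallest, subset A still gave 965 to 1024 calls and subset B 48 to 79 over 5 draws. A larger spread between replicates in subset B stays open. The common biological coefficient of variation was 15.2% there and 16.0% in subset A, while the chi-square per degree of freedom between replicates went the other way, 7.87 for controls and 7.25 for GDF10 in subset B against 5.38 and 6.85 in subset A, and both differences kept their direction in the thinned libraries. Whether both subsets share 1 GDF10 effect at different strengths stays open. Of 941 transcripts called in subset A and kept by the filter over all 8 libraries, 73.5% had the same direction in subset B. The other pairings of the subset B libraries gave at most 67.6%, and only 3 pairings exist. A biological difference between the cultures was not tested, because no label describes one.

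The subsets themselves stand apart by 5763 transcripts, against the 547 called for GDF10 with the subset term. Differences in fragment length are argued against as the whole cause, since the length lost to fragment ends overlapped between subsets. It was 137.3 to 145.4 bases in subset A and 136.1 to 146.0 in subset B. With that length as a covariate 5011 transcripts passed the threshold, and 4892 of the 5763 were among them in the same direction. A covariate so alike in both subsets could take out little of their difference, so those counts add little. The calls were not confined to the 100 most abundant transcripts, which hold 28.1% of reads, since 5675 were called without them. An effect of abundant transcripts on scaling is not decided, because TMM factors already trim the most abundant ones. A transcript length bias is argued against, with 5812 called after a length trend was removed, 5660 of the 5763 among them in the same direction. A separate isolation, culture day or library batch remains possible and cannot be separated from biology, as the labels record none, and no biological explanation was tested.

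The calls for GDF10 that appear once the subsets are modelled were weighed as the last pattern. Reads divided between overlapping transcripts are argued against as the source of 317 of the 547 calls, which had whole counts, since the subset model over all transcripts called 3.84% of the 8252 with whole counts against 3.19% of all. For the 230 calls with divided counts, 2.59% of 8877, that explanation stays open. A transcript length bias is argued against as the whole source, with 532 calls after a length trend was removed, 476 of the 547 among them in the same direction. Of the 18 splits balanced within subsets, 1, the real split, gave as many calls as 547, and the highest other gave 4. Of the 8 splits that part all 4 pairs, 1, the real split, gave as many as 65 under the block, and the highest other gave 0. Both sets of splits are too few for a share under 0.05.

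Without a block the real split gave 0 calls, which each of the 35 splits of the 8 libraries reaches whatever the data hold, so that comparison decides nothing. The split that follows the subsets gave 5017 calls, which points to a structure of the samples, and the highest of the remaining splits gave 2.

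Transcripts under 200 bases took 0.343% of the TPM in control replicate 4, against 0.252% to 0.260% in the other control libraries, and 0.00872% of its reads against 0.00662% to 0.00684%. They took 0.00857% of the reads in GDF10 replicate 3, against 0.00679% to 0.00700% in the other GDF10 libraries. These libraries stood apart by Dixon's test, among 22 groups of 4 values tested, where chance alone marks about 1 in 20 groups.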

How the results depend on the processing

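A 1.5-fold minimum and a test against 1.2-fold could only leave the count of 0 transcripts without a block at 0. That count stayed at 0 with DESeq2 size factors, upper quartile scaling, no filter, the stricter filter and effective length offsets. It ranged from 0 to 1 when 1 library was left out. It became 65 with the replicate block, 155 with DESeq2, 4 with limma-voom and 5 with limma on log2 TPM under either pseudocount. With 1 surrogate variable it became 243. That variable separated replicates 1 and 2 from 3 and 4, and within each subset it was also higher with GDF10. Its values in subset A were -0.393 and -0.414 in controls and -0.278 and -0.313 with GDF10. In subset B they were 0.322 and 0.277 in controls and 0.409 and 0.390 with GDF10. Of the alternatives added after seeing the data, the subset term gave 547, subset A alone 972, subset B alone 42, whole-count transcripts only 4 and length-trend offsets 2. The 3 single calls with a library left out (without GDF10 replicate 1, 2 or 4) were 3 different transcripts with divided counts, none of them named in the report.

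With the replicate block, the count of 65 became 1071 with DESeq2, where 25780 transcripts had a p-value, and 507 among whole-count transcripts. Limma-voom gave 85 and edgeR without the filter 68, and leaving out 1 pair gave 0 to 1. The cause of the larger count among whole-count transcripts was not tested, and the other splits that part all 4 pairs gave at most 0 there. With limma on log2 TPM the block gave 53 calls, 29 higher and 24 lower. With the subset term, the count of 547 became 1586 with DESeq2, where 25780 transcripts had a p-value. It became 536 with limma-voom and 426 in edgeR without the filter. The 4-group model called 1327 for the mean GDF10 effect over both subsets, 717 higher and 610 lower. With 1 library left out, the count with the subset term was 104 to 454, the latter without control replicate 3. It was 104 without control replicate 1, 152 without 2 and 121 without 4, and 212, 142, 234 and 189 without GDF10 replicates 1 to 4. Limma on log2 TPM with the subset term gave 445 calls, 292 higher and 153 lower, a larger share higher than the 260 of 547 in edgeR. DESeq2 also took other transcripts, and limma on log2 TPM other values, so these differences do not isolate the tool. Their cause was not tested.

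The correlation of fold changes between the subsets, across transcripts, was 0.0719, and became 0.0930 with the stricter filter and 0.110 among whole-count transcripts. Each named transcript was tried under 24 alternatives. ENSRNOT00000026793 was past the threshold in 10 of them, ENSRNOT00000021630 in 11, ENSRNOT00000004525 in 6 and ENSRNOT00000071885 in 6, and their highest adjusted p were 0.209, 0.209, 0.299 and 0.341. They were chosen for complete separation of the groups, so their steady direction shows little. The gene list alternatives were not run for want of gene names. At this depth, simulated 2-fold changes of transcripts with at least 100 reads were recovered in 40 of 50 cases without a block, and the smallest simulated changes in 1 of 50. In the same simulation, 15 of 161 calls with the replicate block and 16 of 165 with the subset term were false. Both shares are above the threshold's rate, but 1 simulated data set does not measure a rate over repeats. The counts under these models may hold more false calls than the threshold implies, which stays open.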

Other observations

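The tests in this part were chosen after the data were seen, except the planned leave-outs.

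With the subset term, 15 transcripts changed by at least 2-fold. Of these, 7 had whole counts in every library and 8 had counts divided with other transcripts, close to the makeup of all transcripts tested, of which 8252 of 17129 had whole counts. All 3 that changed by at least 10-fold had divided counts. A candidate explanation is that reads were assigned to one isoform in some libraries and to another in the rest. The 3 calls made when 1 GDF10 library was left out, each with a log2 fold change between -11.15 and -10.00, also had divided counts. Restricting the test to whole-count transcripts moved the calls from 65 of 17129 to 507 of 8252 with the replicate block, from 547 to 761 with the subset term and from 0 to 4 without a block. The size of the move thus depended on the model, and its cause was not tested.

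Short transcripts tended to be lower with GDF10 in the fits counted by length here, which leave out the replicate block. With that block, the transcripts that fell were not shorter. Their median was 3100.5 bases for 36 calls, against 3011 for the 29 that rose. The median log2 fold change of transcripts up to 1257 bases was -0.03 with the subset term and 0.01 for longer ones. In subset A alone 64 short transcripts rose and 121 fell, against 435 and 352 longer ones (two-sided Fisher's exact test over transcripts, p = 5.1e-07). In subset B alone 1 rose and 5 fell, against 17 and 19 (Fisher's exact test, p = 0.214). Among whole-count transcripts 38 rose and 65 fell, against 353 and 305 (Fisher's exact test, p = 0.00200). A length-dependent difference in RNA or library preparation and a change in a class of short messages could each give this, and the removal of a length trend, which left 532 calls in all, cannot separate them.

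The correlation of fold changes between the independent subsets, 0.0719 over 17129 transcripts, was above the largest absolute value of 0.0627 among the other 8 of 9 pairings within subsets. Among whole-count transcripts the observed 0.110 was below the largest absolute value of 0.167 from another pairing. Across whole-count transcripts, which are not independent replicates, the correlation did not set the GDF10 contrast apart from other pairings.

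The 785 transcripts with complete separation of the GDF10 and control libraries were set against other splits. Of the 8 splits that part all 4 pairs, the highest other separated 384 transcripts or 2.24%, and of the 18 balanced within subsets, the highest other separated 409 or 2.39%. Both sets of splits are too few for a share under 0.05.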
